A study of Rattus norvegicus with 18 samples.

How the data were processed

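Germ cells carrying a germ-cell-specific green fluorescent protein were sorted by flow cytometry from Sprague-Dawley rat fetuses, and their DNA was turned into bisulfite libraries enriched for a rat panel of target regions by hybrid capture, per the labels' protocols. Dams were fed a control diet with 18% of energy from fat or a high-fat diet (HFD) with 45%, with 5 dams in each diet group, and the day of a sperm-positive smear counted as gestational day (GD) 0. The labels give 18 samples in 5 groups, namely 4 control males, 3 control females, 4 HFD males and 3 HFD females at GD16, and 4 control males at GD18. The series' design text adds that 4 samples were re-analysed from another project and does not say which group they form. Whether samples of one group came from separate litters is not stated.

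Bowtie2 and Bismark 0.19.0 are named in the submitters' processing notes. The design text says that methylation was extracted per sample and locus, that the loci were cut into segments with a minimum of 50 bp, and that differentially methylated regions (DMRs) were searched among the segments. The genome build is not given in the sources used here, so coordinates are printed as the files give them. The series was analysed from 6 tables of the authors' own comparisons, 4 full DMR lists and 2 lists of regions with a rise of at least 50 points on HFD. Each full list covers 1 comparison: HFD against control in males at GD16, HFD against control in females at GD16, control males against control females at GD16, and control males at GD18 against control females at GD16.

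Per the file headers, each row gives the mean CpG methylation of a case group and a control group as a fraction from 0 to 1, which the authors averaged over samples before deposit. The signed difference of the 2 means is a score deposited by the authors, and its sign matched the 2 means in each table. A p-value from a test the header calls a two-sample t-test and a false discovery rate (FDR) were deposited by the authors for each region. No value per sample, no read count and no coverage was available for use, so the depth behind each methylation level is unknown, no interval is given for a level and no test across replicates was run. Tests planned for values per sample were therefore not made.

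The deposited values were examined for the filters behind them. All listed regions have at least 5 CpGs and an absolute difference of at least 10 points, and the largest deposited FDR lies at 0.05. From the deposited p-values and FDRs, the number of regions each FDR was adjusted over was worked out as FDR times rank divided by p. It came to 2747 regions for the rises and 7674 for the falls in HFD males, 584 and 1496 in HFD females, 48493 for the sex comparison and 1832 for the GD18 comparison. The FDRs were thus adjusted over regions already selected, of which 87.8 to 99.2% were listed, and they are not a genome-wide error rate. The smallest p above 0 was 1.99e-107 and the median p fell with the number of CpGs, so the unit of the authors' test was not the sample alone, and the FDRs say little about the spread between animals. The lists also hold 180, 50, 179 and 58 regions shorter than 50 bp, in the order of the comparisons above.

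Gene names came from a table of rat RefSeq genes (assembly GRCr8), used for names only. A stray bracket was removed from 454 gene identifiers of the HFD male table, after which 94.1 to 94.7% of the distinct identifiers in each full table had a symbol. Genomic features, CpG islands and repeats are those of the deposited annotation.

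Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used. The share of DMRs with higher methylation was given an exact Clopper-Pearson 95% interval and an exact two-sided binomial test against equal shares, both of which treat neighbouring regions as independent and cover counting error over regions only. Lists were intersected with bedtools at a minimum overlap of 1 bp. The overlap was set against 1000 random draws and Fisher's exact test over the 53714 distinct stretches that the DMRs of all tables form. Directions at shared regions, features, chromosomes and gene lists were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family. Categories with fewer than 10 DMRs in a pair of lists were not tested.

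The 11 gene lists were fixed before the data were examined: imprinted genes, germline genes, meiosis genes, pluripotency and primordial germ cell genes, DNA methylation and chromatin machinery, piRNA and transposon silencing genes, sex determination and somatic gonad markers, blood and endothelial markers, lipid, glucose and energy metabolism genes, homeobox and T-box genes, and olfactory and vomeronasal receptors. Their background was the 8242 genes with a DMR in any table, and some genes, such as Tdrd1 and Piwil1, stand in more than 1 list. Named genes followed a rule of the same date. Per comparison these were the genes of the 8 largest differences in each direction, the 5 genes with the most DMRs, up to 4 members of each list by size of difference, the 8 shared regions of each pair of lists with the largest smaller difference, and up to 15 named regions of each 50-point table.

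The gene list test was tested on simulated data over the 8242 background genes. A planted list of 40 genes, with the odds of a DMR changed 5 times, was called in 97.0%, 94.0%, 74.0% and 83.0% of 100 draws at the DMR rates of HFD males, HFD females, the sex comparison and the GD18 comparison, and random lists in at most 0.6%. A planted list of 10 genes was called in only 26%, 22%, 17% and 23% of draws. Since 10 of the 11 lists have 7 to 34 background genes, a list that did not pass may still differ. Alternatives were a stricter FDR, larger differences, merging of neighbours within 1000 bp, autosomes only, larger overlaps, length weights, promoter DMRs only and other backgrounds. A minimum of 10 CpGs, joint Benjamini-Hochberg and Bonferroni adjustment and a background of sex DMR stretches were added after seeing the data. The comparison of feature shares between the GD16 sex list and the GD18 list was also added then.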

Results

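The data describe DNA methylation in fetal rat germ cells, called gonocytes in the labels, during the period in which germ cells erase most of their methylation. Capture bisulfite libraries from 18 sorted samples form 5 groups, which are control males (4 samples), control females (3), HFD males (4) and HFD females (3) at GD16, and control males at GD18 (4). All methylation levels below are the authors' group means for a region, in percent, and their depth and their spread between animals are unknown. A region is said to be higher or lower where the authors listed it as a DMR. The 4 full tables list 48127 regions between control males and females at GD16, 10084 between HFD and control males, 1832 between HFD and control females, and 1618 between GD18 control males and GD16 control females.

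**Figure D1:**
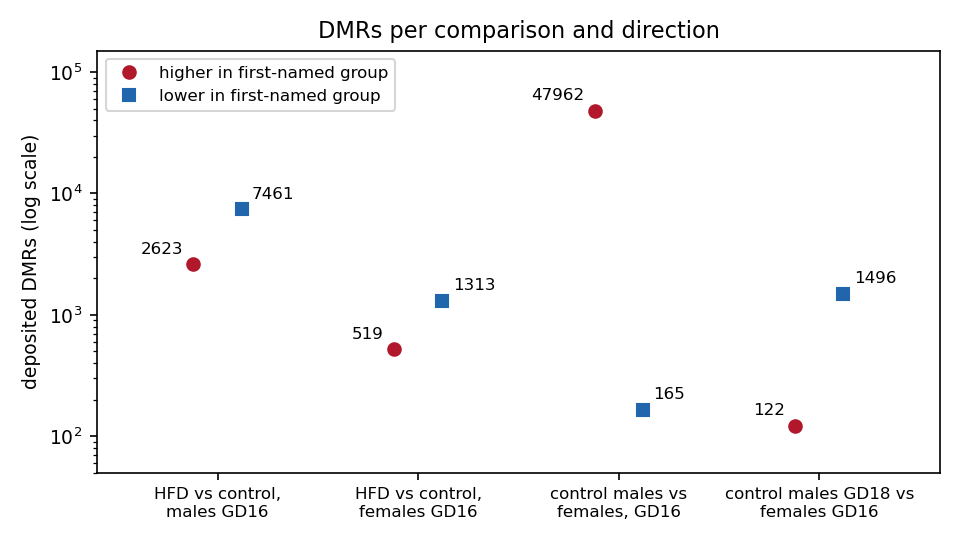
Number of deposited DMRs (vertical axis, log scale) in each of the 4 comparisons (horizontal axis), split into regions higher (circles) and lower (squares) in the first-named group. Control males were higher than control females at 47962 of 48127 regions at GD16, while HFD males were lower than control males at 7461 of 10084.

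The first comparison asks whether male and female germ cells hold the same methylation at GD16. Control male germ cells were more methylated almost throughout, with 47962 DMRs higher in males and 165 higher in females. The share higher in males was 99.7% (exact 95% interval 99.6 to 99.7%). Over the male-higher regions the authors' means had a median of 19.6% in males (quartiles 17.0 and 23.4%) and 4.7% in females (quartiles 3.3 and 6.3%). Over the 165 female-higher regions the medians were 7.7% in males and 26.2% in females. Of all listed differences, 17.4% reached 20 points and 2.08% reached 30 points, so most were moderate.

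Among regions with a gene name the largest male excess lay in an intron of Pdss2, a subunit of the enzyme that makes the coenzyme Q side chain, at chromosome 20, 48167592 to 48167682, with 92.3% in males and 0% in females in the authors' deposited table. Lima1, an actin-binding protein, had 92.9% against 6.0% at its promoter (chromosome 7, 141494826 to 141494918), also in the authors' deposited table. Introns of Zc3h15 (84.8% against 0%) and Usp14, a deubiquitinase of the proteasome (84.7% against 0%), came next among named regions in the authors' deposited table. The authors' deposited table further gave 81.5% against 2.2% in an intron of Slc49a4, 79.2% against 0% in an exon of the sodium channel gene Scn2a, 77.2% against 0.7% in an exon of Cnga1, a channel of rod photoreceptors, and 73.4% against 0% in an intron of the transporter gene Abcc5. Long genes collected the most regions, with 89 DMRs at Camta1, 69 at Tenm2, 57 at Ank3, 55 at Abcc4 and 53 at Tenm3, each of them higher in males.

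Female-higher regions were few and short, with a median length of 138 bp against 442 bp for the male-higher ones. At 151 of the 165, over the same coordinates, control females also exceeded GD18 control males. The control female libraries are the same in both comparisons, so chance highs of that group could give both. The 7 largest female excesses lay in regions without a gene name. In the authors' deposited table an exon of the growth factor receptor gene Fgfr4 (chromosome 17, 9998048 to 9998179) had 52.2% in females and 7.7% in males. Zfp521, a zinc finger transcription factor, had 67.6% against 24.0% in an intron, and the potassium channel gene Kcnd2 54.9% against 12.5% in an exon, in the authors' deposited table. Further female excesses with a gene name in the authors' deposited table lay in the 5' UTR of Klhdc8a (50.0% against 7.0%), at the transcript end of Siah3 (57.4% against 15.3%), in an intron of Kazn (59.6% against 19.8%), in an exon of Numa1 (40.4% against 5.6%) and in an intron of Nos1ap (47.2% against 13.9%). CpG islands made up 4.24% of the female-higher regions (7 of 165) and 0.277% of the male-higher ones (133 of 47962), and introns 21.2% against 37.0% (Fisher's exact test, adjusted p = 3.60e-06 and 1.26e-04).

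The male excess ran through all 11 gene lists. Of the imprinted genes, 28 of 29 background genes had a DMR and 108 of 109 regions were higher in males, with examples at Trappc9 (41.4% in males against 2.8% in females) and Sfmbt2 (35.6% against 4.8%) in the authors' deposited table. All 39 regions of 17 germline genes were male-higher, among them Piwil1, which binds piRNAs (31.9% against 2.0%), and Sohlh2, a germline transcription factor (28.3% against 3.1%), in the authors' deposited table. Each of the 15 regions of 10 meiosis genes was male-higher, including Mlh3 (34.4% against 8.0%) and Hormad1 (25% against 4.0%) in the authors' deposited table. The 33 regions of all 13 methylation and chromatin genes were male-higher as well, and the authors' deposited table gave 26.0% against 2.7% over 33 CpGs of an intron of Dnmt3a, a de novo DNA methyltransferase, and 30.3% against 1.0% at Tdg, a glycosylase of active demethylation. Pluripotency and primordial germ cell genes had 20 of 21 regions higher in males, led in the authors' deposited table by the receptor gene Kit (22.5% against 0.8%) and the Tcl1a promoter (28.9% against 7.8%).

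Markers of other cells followed the same direction. The 18 regions of 9 somatic gonad genes, such as Cyp11a1 (26.0% in males against 1.5% in females) and Nr5a1 (22.6% against 2.6%), were male-higher in the authors' deposited table, as were the 19 regions of 7 blood and endothelial genes, such as Runx1 (26.7% against 3.8%). So were all 134 regions of 33 metabolism genes (Glp1r, 42.4% against 11.1%), 44 of 16 homeobox and T-box genes (Tbx20, 34.8% against 3.2%), 100 of 89 olfactory and vomeronasal receptors (Vom2r36, 35.1% against 4.7%) and 31 of 11 piRNA genes (Tdrd1, 26.1% against 5.4%) in the authors' deposited table. No list had a share of genes with a DMR that differed from the other genes (Fisher's exact test, smallest raw p = 0.3434, adjusted p = 1.00), and no list differed in direction (smallest adjusted p = 0.6537). Since 7820 of the 8242 background genes had a DMR in this comparison, a list could hardly stand above the others. The test therefore does not show whether any class of genes is favoured.

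The second comparison sets control males at GD18 against control females at GD16, so day and sex differ together. The series' design text does not say which group its 4 re-analysed samples form, so the project of origin may differ here as well. The GD16 control males and HFD males also have 4 samples each, so the same doubt holds for the comparisons that use them. Here the direction was the other way. Only 122 regions were higher in GD18 males and 1496 were lower, a share higher of 7.54% (exact 95% interval 6.30 to 8.94%, binomial p = 5.49e-301). At the lower regions the authors' means had medians of 3.0% in GD18 males and 16.5% in GD16 females, and at the higher ones 13.2% and 0.95%. The sex comparison at GD16 listed 29.7 times as many regions. No deposited table compares GD16 with GD18 males.

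Among regions with a gene name, falls were led in the authors' deposited table by introns of the synaptic gene Rimbp2 (6.8% in GD18 males against 68.9% in GD16 females), Zfp521 (6.0% against 67.6%) and the ubiquitin ligase gene Trim2 (8.4% against 68.0%). Siah3 (1.4% against 57.4%), Kazn (9.1% against 59.6%), Kcnd2 (4.5% against 54.9%), Fgfr4 (2.3% against 52.2%) and Klhdc8a (4.3% against 50.0%) followed in the authors' deposited table, and these 5 and Zfp521 were also female-higher at GD16. Larger falls lay in 5 regions without a gene name. Rises in regions with a gene name were smaller, with Leo1, a subunit of the Paf1 transcription complex, at 25.9% against 0% in an intron (chromosome 8, 82387827 to 82387874), Qprt at 21.7% against 2.1% and the X-linked Mageb4 at 17.3% against 0.9% in the authors' deposited table. Cnga1, whose exon stood at 77.2% in GD16 males, had 16.6% in GD18 males over the same coordinates in the authors' deposited table.

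Each of the DMRs in the fixed lists was lower in GD18 males. Meiosis genes had 3 members with a DMR in the authors' deposited table, namely Rec114 (4.0% against 35.9%), Rec8, the meiotic cohesin (2.6% against 31.3%) and Prdm9, which places recombination sites (1.8% against 14.0%). That share, 27.3% of 11 background genes against 7.47% of other genes, did not pass after adjustment (exact raw p = 0.0440, adjusted p = 0.2622). Imprinted genes with a DMR were Plagl1 (2.5% against 22.3%), Ppp1r9a (2.5% against 21.3%), Asb4 (1.8% against 15.2%) and Nap1l5 (2.3% against 12.8%) in the authors' deposited table. Among pluripotency and germ cell genes Prdm1 (3.6% against 18.8%) and Dppa3 (3.7% against 14.4%) were listed, and Tdg had 2 lower regions, the larger at 3.9% against 14.7% in the authors' deposited table. Single or few regions stood at Tdrd1 (3.3% against 14.3%), Runx1 (5.7% against 20%), Ucp2 (1.0% against 14.0%), Igf1r (3.7% against 15%), Ppard (7.7% against 18.1%), Pax7 (5.1% against 18.4%), Six4 (1.7% against 13.5%) and the olfactory receptor Or13j1 (3.1% against 17.5%) in the authors' deposited table. No somatic gonad gene had a DMR here. Promoters held 4.20% of these DMRs against 2.29% in the GD16 sex comparison, and introns 29.9% against 37.0% (exact test, adjusted p = 2.15e-05 and 3.28e-08).

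The third comparison asks what maternal HFD does to male germ cells at GD16. Methylation was lower on HFD at 7461 regions and higher at 2623, so that 26.0% of the regions rose (exact 95% interval 25.2 to 26.9%). At the regions that fell the authors' means had medians of 10.3% on HFD and 25.2% on control diet, and at those that rose 27.7% and 10.5%. A fall predominated on the X chromosome too, with 108 lower regions and 52 higher. Transcript 3' UTRs were rarer among rises than among falls (0.839% against 1.65%, exact test, adjusted p = 0.0152), and no chromosome differed between the directions (smallest adjusted p = 0.1882). Among differences of at least 50 points the directions were close to even, with 49 rises and 54 falls, a share higher of 47.6% (exact 95% interval 37.6 to 57.6%).

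Extreme rises with a gene name lay in short regions of few CpGs. In the authors' deposited table an intron of Gsg1, a germ cell gene, went from 1.3% to 100% over 5 CpGs (chromosome 4, 169028908 to 169028991), an intron of Lpin1, a phosphatidate phosphatase of lipid synthesis, from 0% to 98.3% over 6 CpGs (chromosome 6, 41819975 to 41820061), and an exon of the anion channel gene Lrrc8a from 0% to 92.9%. Cmtm8 (20.2% to 95.8%), Aebp1 (6.5% to 75.8%), Zfp652 (0% to 66.5%), the keratin gene Krt14 (37.6% to 100%) and the synapsin gene Syn3 (0% to 62.1%) came next among named regions in the authors' deposited table. The 50-point table of males held 49 regions with a median of 5 CpGs, 19 of them intergenic. It added Slc24a4 (0% to 75%), Rexo2 (22.9% to 83.3%), Timd2 (0% to 59.2%), Otop2 (2.3% to 61.3%), Scn3a (15.6% to 74.3%), Tbc1d24 (12.7% to 69.3%) and Epm2a (12.8% to 68.5%), per the authors' deposited table.

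Falls of similar size were found, among others, in an intron of Bach2, a transcriptional repressor of lymphocytes (chromosome 5, 47656371 to 47656430, 100% to 4.0%), and in introns of Unc79 (91.7% to 1.3%), Magi2 (100% to 21.2%), the glutamine transporter gene Slc38a1 (77.9% to 0%) and Pdss2 (92.3% to 25.1%) in the authors' deposited table. Exons of the myosin gene Myh8 (75% to 0.7%), Scn2a (79.4% to 7.2%) and Ahdc1 (76.0% to 4.0%) fell as well in the authors' deposited table. Ank3 collected 15 DMRs, 9 of them lower on HFD, and Abcc4, Camta1, Ctdspl and Foxn3 collected 12 each, with 9, 10, 7 and 9 lower.

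Falls outnumbered rises in 10 of the 11 lists, with 18 of 20 regions lower in imprinted genes, 17 of 20 in metabolism genes and 5 of 5 in pluripotency and germ cell genes. Imprinted examples in the authors' deposited table were Sfmbt2 (36.9% to 8.1%) and the promoter of Plagl1 (22.4% to 1.1%), against a rise at Zim1 (0% to 25.5%). The insulin receptor gene Insr (47.9% to 5.3%), the coactivator gene Ppargc1a (36.9% to 3.3%), the acetyl-CoA carboxylase gene Acacb (35.2% to 7.1%) and Glp1r (36.4% to 17.2%) fell in the authors' deposited table. The Tcl1a promoter (43.3% to 8.0%) and Kit (26.1% to 4.9%, with 4 regions, all lower) fell too in the authors' deposited table. Chromatin genes went both ways, with falls at Mbd3 (46.8% to 15.3%) and Tdg (38.9% to 8.3%) and rises at Ehmt2, a histone H3 methyltransferase (8.6% to 36.9%), and Kdm1b, a histone demethylase (17.4% to 42.4%), in the authors' deposited table. Among germline, meiosis and piRNA genes, Tdrd1 (2.7% to 31.5%), Tex101 (0% to 15.6%) and Piwil2 (11% to 23.7%) rose, and Piwil1 (42.1% to 20.4%), Tuba3a (31.5% to 12.6%), Tdrd7 (19.4% to 7.3%) and the Msh4 promoter (32.1% to 3.2%) fell in the authors' deposited table.

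Somatic markers showed both directions, with a rise at Pdgfra (14.5% to 47.7%) and a fall at Cyp11a1 (26.6% to 5.7%), and the 4 blood and endothelial regions fell, at Tie1 (53.9% to 34.7%), Hbb (20.6% to 3.6%), Runx1 (25.4% to 14.9%) and Cdh5 (17.0% to 6.5%), in the authors' deposited table. Developmental genes fell at Pax5 (44.7% to 8.6%) and Tbx20 (35.1% to 15.4%) and rose at Pax2 (14.0% to 37.5%) and Tbx5 (4.2% to 26.4%) in the authors' deposited table. Regions of the same gene did not always share a direction, with 1 higher and 1 lower region at Ehmt2, Kdm1b, Piwil1 and Tbx5 and 1 higher and 2 lower at Pdgfra and Insr. No list departed from the other genes in direction (exact test, smallest adjusted p = 0.9298). Only olfactory and vomeronasal receptors departed in the share of genes with a DMR, 18.8% (18 of 96) against 35.8% of other genes (exact test, adjusted p = 0.0040), with a rise at Or52h2 (0% to 42.1%) and a fall at Or8s8 (29.1% to 9.2%) in the authors' deposited table. Counted over DMRs and not genes, that difference was gone (18 of 120 regions, odds ratio 0.931, exact test, adjusted p = 1.00).

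The fourth comparison asks the same of female germ cells. Methylation was lower on HFD at 1313 regions and higher at 519, a share higher of 28.3% (exact 95% interval 26.3 to 30.5%, binomial p = 3.74e-79). At the regions that fell the authors' means had medians of 2.4% on HFD and 16.1% on control diet, and at those that rose 15.2% and 2.0%. Males had 5.50 times as many HFD DMRs as females, a ratio for which no test is possible without values per sample, and the male lists come from 4 samples a group against 3. Whether the male table was aligned and filtered like the female one is not given in the sources used here, and it holds 118 DMRs on unplaced scaffolds against 1 in females. On autosomes alone the counts were 9803 and 1798. The ratio does not compare the sexes on equal terms, because a listed fall needs at least 10 points. Control females had a median of 4.7% (upper quartile 6.3%) over the regions higher in control males, so most could not fall that far there. In males 5219 of the 7461 falls overlapped such regions.

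Among regions with a gene name, rises in HFD females were led in the authors' deposited table by introns of Tenm3, a teneurin (0% to 70.0%, chromosome 16, 46594560 to 46594583), the homeobox gene Cux2 (0% to 50.0%) and the calcium-binding protein gene Calb1 (8.9% to 56.4%), the first 2 being the named regions of the 50-point table. Map1b (2.0% to 47.0%), the acrosin gene Acr, whose product is a sperm protease (4.1% to 42.9%), Trim71 (22.3% to 59.8%), Prkcel1 (3.6% to 39.1%) and the phosphofructokinase gene Pfkm (0.9% to 35.6%) followed in the authors' deposited table. Larger falls than any named here lay in 6 regions without a gene name. The named falls were led by Abcc4 (75.5% to 0%, intron, chromosome 15, 103703122 to 103703520), Stub1, a ubiquitin ligase of chaperone clients (72.6% to 1.3%), the sulfonylurea receptor gene Abcc8 (59.4% to 1.9%) and the promoter of Pogk (59.7% to 3.4%) in the authors' deposited table. The pyruvate kinase gene Pklr (54.2% to 0%), the neurotrophin receptor gene Ntrk2 (54.1% to 2.5%), Siah3 (55.2% to 6.6%) and Kazn (52.4% to 4.3%) also fell in the authors' deposited table. Abcc4 and Camta1 had 6 DMRs each, with 4 and 3 of them lower, Itpr2 and Kalrn 4 each and Cdk6 3.

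Few listed genes had a DMR in females. Wnt4, which directs ovarian development, rose in an exon (7.8% to 40%), Sohlh2 rose (2.7% to 21.8%), Rec8 fell (31.3% to 0.5%), and Pax2 fell (41.2% to 1.1%) in the authors' deposited table. Prdm1 fell over 18 CpGs (15.7% to 1.2%) and Esrrb rose (2.8% to 13.7%), Slc22a3 rose (8.8% to 21.3%) and Ppp1r9a fell (12.1% to 0.7%) in the authors' deposited table. Of 4 metabolism genes, Ppard (15.5% to 1.0%), Fto (13.7% to 1.6%) and Ucp2 (11.7% to 1.4%) fell and Acacb rose over 27 CpGs (2.6% to 13.5%) in the authors' deposited table. Cldn11 (17.1% to 5.4%) and Runx1 (22.9% to 3.3%) fell in the authors' deposited table, and no methylation machinery or piRNA gene had a DMR. The olfactory list had 0 of 96 genes with a DMR against 8.47% of others (exact test, adjusted p = 0.0058). Over DMRs this difference did not pass (exact raw p = 0.0816, adjusted p = 0.7114). No other list passed (exact test, smallest adjusted p = 0.6098).

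HFD regions were then set against those of the other comparisons. In males, 5773 HFD regions overlapped a region higher in control males than in control females, and 5219 of these were lower on HFD (90.4%, exact 95% interval 89.6 to 91.2%). The 4286 HFD regions outside any sex DMR were nearly even, with 2241 lower (52.3%, exact 95% interval 50.8 to 53.8%). Among the 25 that overlapped only a female-higher region, 24 were higher on HFD. Sorting by sex DMR selects on the control male level, which the HFD difference also subtracts. Regions with high control males are those with room to fall. Selection could thus give part of the contrast between 90.4% and 52.3%, and how much was not measured. At 1089 segments with the same coordinates in both tables that were lower on HFD and higher in control males, the medians were 25.5% in control males, 10.4% in HFD males and 5.0% in control females. The control male level is that of the sex table, since the 2 tables gave the same control male mean at 917 of all 1153 identical segments and differed by up to 13.5 points at the others. The control male libraries enter both comparisons. Of the 5980 overlapping pairs, 90.6% had opposite directions. Simulated regions with no difference between any groups gave 87.9 to 99.96% for standard deviations of 3 to 10 points, a range that the share does not exceed. That simulation holds no sex difference, so its range does not measure what shared controls give here. The near-universal male excess also leaves little room for other directions. The stretches lower on HFD and higher in males numbered 5113, against 6499 for independent lists over the 53714 stretches. Of these stretches 47649 hold a sex DMR, and each of the others comes from another list. The overlap is thus pushed below the independent value by construction, so the shortfall is no sign of avoidance.

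In females the split ran the other way, which the shared control libraries alone could give. Of the 410 HFD regions of females that overlapped a region higher in control males, 123 were lower on HFD (30%), and all 95 that overlapped only a female-higher region were lower. Outside sex DMRs 1095 of 1327 were lower on HFD (82.5%). The control female libraries are the control group of both of these comparisons, so their chance highs give the same direction in both. Control males are the control of the HFD comparison but the case of the sex comparison, so theirs give opposite directions. The reversed split therefore does not show a different response to diet by sex. Of the 516 overlapping pairs in females, 75.8% had the same direction, below the 87.9 to 99.96% of the simulation, which holds no sex difference.

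**Figure D2:**
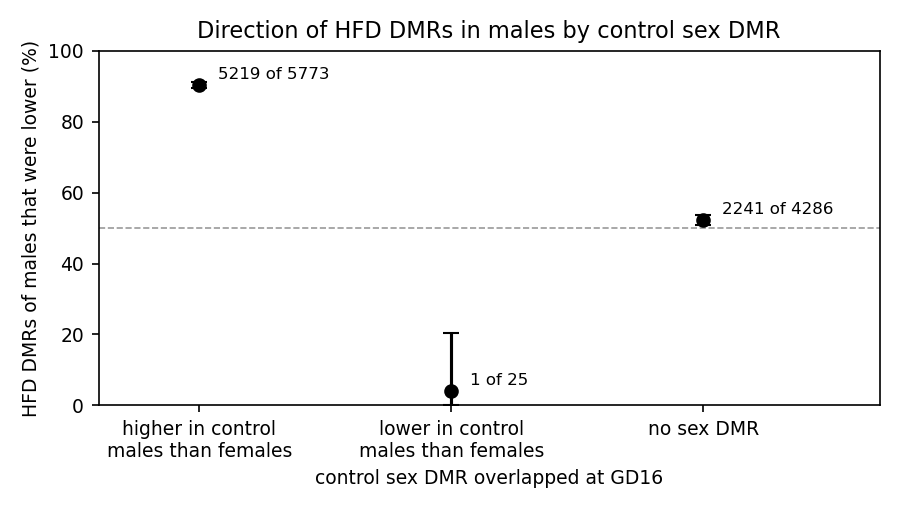
Share of HFD DMRs in males that were lower on HFD (vertical axis, percent, with exact 95% intervals over regions) by the kind of control sex DMR they overlapped at GD16 (horizontal axis); the dashed line marks 50%. The share was 90.4% at regions higher in control males and 52.3% outside sex DMRs. Sorting by sex DMR also selects on the control male level, which could give part of this contrast.

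The named shared regions were picked for large differences in both comparisons, so a wide gap between HFD and control males was set in advance. HFD males lay below control males there, and not always above control females. At Scn2a the authors' deposited table gave 79.4% in control males and 7.2% in HFD males, and 0% in control females. Identical segments of Lima1 (92.9%, 29.9% and 6.0%), Myh8 (75%, 0.7% and 12.2%), Ss18 (64.7%, 3.0% and 4.2%), Sgms1 (60.3%, 3.0% and 0%) and Fbxl13 (55.2%, 0% and 0%) had these means in control males, HFD males and control females in the authors' deposited table.

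The HFD lists of males and females share no library. They overlapped in 293 pairs of regions, 168 of them in the same direction (57.3%). No dependence of direction in males on direction in females was found (odds ratio 1.12, exact p = 0.6894). This does not show independence, as no interval was made for the odds ratio. Trim71 (38.9% to 6.0% in males, 22.3% to 59.8% in females), Defb23 (39.9% to 11%, 5.8% to 36.9%) and Otof (35.6% to 10.1%, 5.6% to 29.3%) fell in males and rose in females in the authors' deposited table. Pax2 (14.0% to 37.5%, 41.2% to 1.1%), Itpr2 (9.6% to 33.4%, 34.1% to 2.1%), Txndc5 (9.9% to 33.1%, 34.5% to 1.8%) and Kalrn (7.1% to 28.1%, 34.2% to 1.8%) rose in males and fell in females, and Kif26b fell in both (39.7% to 11%, 33.8% to 0.6%), in the authors' deposited table. Whether the 2 lists overlap more than chance depended on the background. Over all 53714 stretches they shared 290 against 338 for independent lists (odds ratio 0.826, exact test, adjusted p = 0.0035), and over stretches with a sex DMR alone the odds ratio was 2.45.

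HFD females and GD18 males were lower than the same control females at many of the same regions. Of 565 overlapping pairs, 557 were lower in both. The 549 stretches lower in both compare with 36.3 for independent lists. Of the pairs, 99.6% had the same direction, within the 87.9 to 99.96% that simulated groups without any difference gave against a shared control. The other pairs of lists that share the control females lay below that range. They had 75.8% (HFD females with the GD16 sex list) and 49.6% (sex list with the GD18 list). The simulation therefore does not measure what shared controls give here. Of the 183 segments with the same coordinates in the HFD female and GD18 tables, 178 were lower in both HFD females and GD18 males. Their medians were 20.3% in control females (GD18 table), 2.7% in HFD females and 3.7% in GD18 males. Cox4i1 (41.8% in control females, 1.5% in HFD females, 3.3% in GD18 males), Fam163a (40.2%, 2.2% and 5.3%), Nos1ap (48.5% or 47.2%, 3.1% and 2.5%) and Lrp1 (42.9%, 11.6% and 5.0%) are examples from the authors' deposited table. Control females also stood above GD16 control males at 151 of 498 pairs of the sex and GD18 lists, where they exceeded GD18 males as well. These 151 are identical segments and make up most of the 165 female-higher regions of the sex list. At 217 identical segments where GD16 males were higher than the females and GD18 males lower, the medians were 30.1% in GD16 males, 14.5% in GD16 females and 2.7% in GD18 males. The control female libraries could not be split, so what they add to these overlaps was not measured.

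**Figure D3:**
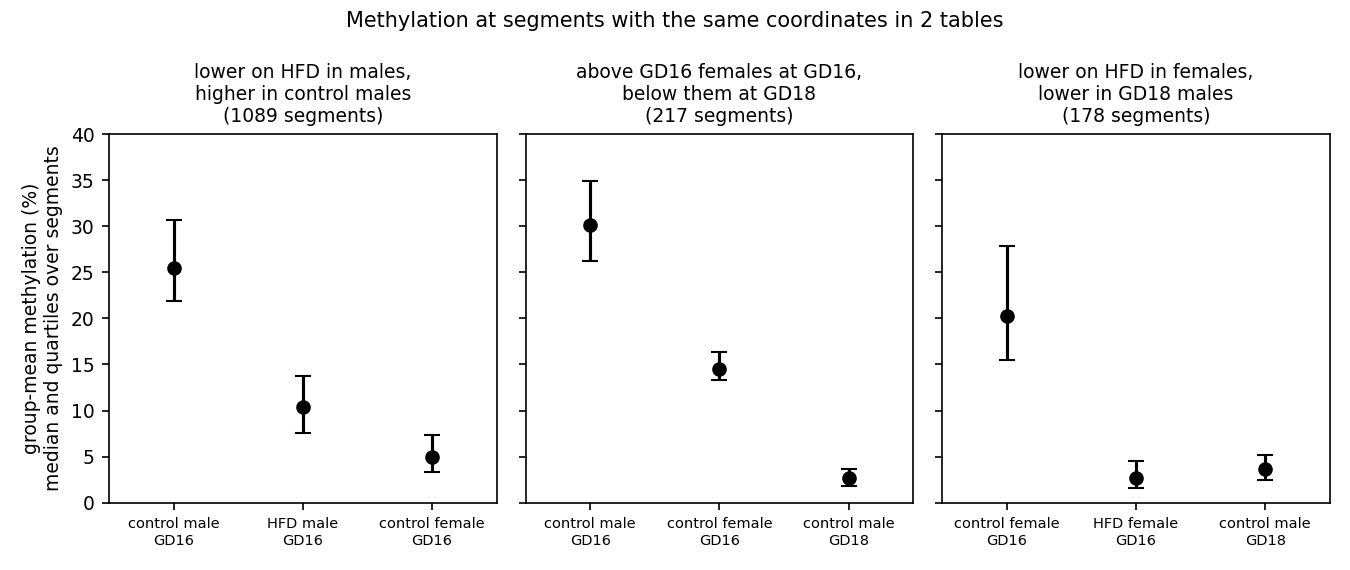
Authors' mean methylation (vertical axis, percent) per group (horizontal axis) at segments with the same coordinates in 2 tables, as medians with quartiles over the 1089, 217 and 178 segments with the directions named above each panel. The selection by direction fixes control males as highest in the first panel, the whole order in the middle one and control females as highest in the last. In the first panel HFD males lie at 10.4% and control females at 5.0%, and GD18 males lie at 2.7% in the middle one.

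Between GD18 males and HFD males, whose lists share no library, 270 pairs overlapped and 181 had the same direction (odds ratio 0.564, exact test, adjusted p = 0.4434). C13h1orf115 (44.8% to 2.4% on HFD in males, 38.9% in GD16 females and 1.8% in GD18 males) and Prkcz (65.1% to 29.7%, 36.0% and 9.3%) were lower in both, and Ppil1 (9.1% to 35.7%, 27.2% and 2.3%) went both ways, in the authors' deposited table. The intergenic share was 50.0% in HFD males, 54.6% in HFD females, 49.1% in the GD16 sex list and 54.3% in the GD18 list. The HFD list of females held more intergenic and fewer intronic regions than that of males (54.6% against 50.0%, exact test, adjusted p = 0.0020, and 31.3% against 34.7%, adjusted p = 0.0173).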

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

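Chosen only after results had been seen were the test of HFD males against control females, the use of the direction in females to judge a diet effect, both tests of the 50-point differences, the comparisons of direction shares between lists, and the checks on selection and on the sex difference that set tests aside. No group had values per sample, so no sample was tested as an outlier.

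The share of HFD DMRs with higher methylation differed between the sexes by the test of the difference itself, at 26.0% in males and 28.3% in females (Fisher's exact p = 0.0407, odds ratio 0.889), which counts neighbouring regions as independent. The order turned with size, to 39.4% in males and 23.3% in females at 30 points or more and 47.6% and 17.4% at 50 points or more, so which sex has the larger share depends on the cut. Intergenic regions were more frequent in the HFD list of females (exact test, adjusted p = 0.0020) and introns in that of males (adjusted p = 0.0173). The share of DMRs higher in males than in GD16 females was 99.7% for GD16 males and 7.54% for GD18 males, an odds ratio of 3564.

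Mitochondrial DNA appears only in the HFD table of males. Both of its regions there were higher on HFD in the authors' deposited table, by 16.5 points at positions 6225 to 6640 (18.2% against 1.7% over 20 CpGs) and by 13.4 points at positions 14383 to 14708 (15.4% against 2.0% over 18 CpGs). The 1 region on the Y chromosome fell from 32.5% to 11% in the authors' deposited table. Unplaced scaffolds held 118 DMRs in the HFD table of males and 1, 38 and 7 in the HFD table of females, the GD16 sex table and the GD18 table.

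HFD-lower regions in males lay mostly where control males exceed control females, 5219 of 7461 or 70.0%. Chance highs of the control male libraries stay open. HFD males were below control females at 12.6% of the 1081 shared segments where they differed (exact 95% interval 10.7 to 14.7%), but this test decides nothing, because males were also higher at 42146 of the 42283 sex DMRs that meet no HFD DMR. Other cells in the sorted control males stay open. Of the promoter DMRs of germline, meiosis and piRNA genes, 4 of 5 (80.0%, exact 95% interval 28.4 to 99.5%) were lower on HFD. They lay at Msh4, Tuba3a, Piwil4 and Rec114, with a second Rec114 region higher. Since 185 of all 239 promoter DMRs in males were lower on HFD too, this share decides nothing. A lowering by the diet stays open too, and females, which share no library with males, gave an odds ratio of 1.12 for the same direction (exact p = 0.6894). In females 287 of 410 HFD regions at male-higher regions were higher on HFD, but with males higher at nearly all sex DMRs this direction does not separate the explanations. Without values per library these explanations, and a difference in project of origin, cannot be told apart.

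Control females stood above both HFD females and GD18 males at 552 regions of the HFD table of females. Among the 147 of these with a GD16 sex DMR, control females exceeded control males at 93, or 63.3% (exact 95% interval 54.9 to 71.1%). This share lies above the bound of 50% that was written beforehand against regions which both sexes lose late, but the bound was wrong, because it left out that the regions were selected for high control females. In the HFD table of females, control females exceeded control males at 96 of the 218 HFD-lower regions with a sex DMR and at 0 of the 287 HFD-higher ones, so the share follows the direction the regions were selected for. A requirement of a sex DMR at most of the 552 regions, of which 405 have none, had also been tried after the value was seen. Chance highs of the control females, late loss, an effect of diet and an effect of day or project therefore cannot be told apart here.

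Differences of at least 50 points in HFD males were concentrated in regions of few CpGs. They made up 2.15% of the regions of 5 CpGs (53 of 2464, exact 95% interval 1.62 to 2.80%) and 0.269% of those of 9 or more (9 of 3349, 0.123 to 0.510%). Few CpGs and reads behind a short region would give this. The median difference of all listed regions also fell, from 17.8 points at 5 CpGs to 11.3 at 21 or more. Short regions may need a larger difference to be listed, which would give the same excess, so the shares do not settle the cause. Of these differences 47.6% were rises (exact 95% interval 37.6 to 57.6%), which leaves out the 26.0% of all regions. This cannot decide whether the shift seen elsewhere carries over, because a fall of 50 points needs a control level of at least 50%. Control males at the falling regions had a median of 25.2% and an upper quartile of 30.1%, so most could not fall that far. Coverage would decide whether Gsg1, Lpin1 or Bach2 belong to this class, and it was not available for use. That diet shift was the only biological explanation tested for this pattern.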

How the results depend on the processing

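The minimum of 10 CpGs, joint and Bonferroni adjustment and sex-DMR stretches were chosen only after results were seen. Across 140 alternative settings of 46 results, 96 kept direction and side of the threshold or size. The direction of each of the 4 lists held under every alternative, and only the share in HFD males lost its test, at 50 points or more (47.6%). Counts fell at 30 points to 705, 133, 999 and 61 (HFD males, HFD females, GD16 sex, GD18) and at 50 points to 103, 23, 63 and 13. At 0.1 of the largest FDR they fell to 995 in HFD females and 811 at GD18. The 5-CpG minimum removed nothing, since every listed region has at least 5 CpGs, so its settings were bound to count among the 96. A minimum of 10 CpGs left 2624, 384, 20089 and 336 regions, with 16.4% higher in HFD males and 1.49% at GD18, where 30 points left 1.64%. Bonferroni left 2755, 269, 24033 and 198, in the same order. Weighted by length, mean methylation moved from 15.4% to 14.3% (HFD) and from 22.7% to 22.3% (control) in the male list. In the female list it moved from 7.07% to 6.37% (HFD) and from 14.7% to 13.2% (control). For males of the sex list it moved from 20.7% to 19.97%, and at GD18 the weighted means were 4.02% and 16.3%. Moves were judged against an interval that takes regions as independent, so small ones count. Against all distinct stretches, the odds ratio of the HFD male list turned to 1.04 for intergenic and 0.903 for intronic regions. Lists passing numbered 0 for promoter DMRs and for tests over DMRs in both HFD tables, and 1 at GD18 (olfactory receptors, exact test, adjusted p = 0.0479) against sex-DMR genes. That background drops the 2 olfactory receptors with a GD18 DMR, Or10ak14b and Or13j1, which leaves 0 of 89. Over all background genes the list had 2 of 96 (exact test, adjusted p = 0.2622). Over stretches with a sex DMR the odds ratio of the HFD male list turned to 2.45 with HFD females and 2.91 with GD18 males. A background made of the lists themselves lowers such ratios by construction. At 30 points or more the same-direction share was 100% for GD18 males with HFD females and with the sex list, where too few other pairs were left for the test to pass. The causes of the other changes were not tested. No paired analysis was possible because the tables hold group means only, and leaving out replicates could give no value for the same reason. The unknown depth limits every level, most of all in regions of few CpGs.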

Other observations

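The tests of features between the GD18 list and the GD16 sex list were not planned and were chosen after the data had been seen. Repeats and chromosomes add to the picture of the lists. LTR elements, retrotransposons of the retroviral type, made up 0.803% of the GD18 list and 0.384% of the GD16 sex list (exact test, adjusted p = 0.0441), and CpG islands 1.24% against 0.291% (adjusted p = 1.78e-06). At the 20 CpG island regions of the GD18 list the authors' means had medians of 1.75% in GD18 males and 21.3% in GD16 females. SINE elements held 3.17% of the HFD DMRs in males and 3.17% in females, with 31.6% and 32.8% of these regions higher on HFD.

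The X chromosome held 526 regions of the GD16 sex list, 523 of them higher in males, with medians of 20.9% in males and 4.85% in females. In the HFD table of females it held 33 regions, 13 of them higher on HFD. At 96 segments that were higher in males than in GD16 females at both days, the medians were 22.9% in GD16 males, 13.2% in GD18 males and 1.25% in GD16 females.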
